A study of Drosophila melanogaster with 30 samples.

How the data were processed

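The series covers 30 samples of Drosophila melanogaster. Contact maps were made from embryos (8 samples) and wing discs (6 samples), RNA-seq from wing discs (9 samples), and CUT&Tag from wing discs (7 samples, not analysed here). Per the labels' protocols, samples for the contact maps were fixed with formaldehyde and then with DSG and EGS, and RNA was extracted from 30 wing discs per replicate with TRIzol. The name of the contact assay, the genome build, the strand setting of the RNA counting and the tools' versions are not given in the sources used here. Coordinates are those of the authors' loop lists, written 1-based.

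The submitters' processing notes name featureCounts and DESeq2 for RNA-seq, BWA, bedtools and DESeq2 for the contact maps, and SEACR for CUT&Tag. The RNA table holds raw counts of reads per gene as deposited by the authors, for 17868 genes and 9 libraries. The loop tables hold raw counts of contacts per loop as deposited by the authors, for 186 embryo loops with anchors of 1600 bp and 209 wing disc loops with anchors of 5000 bp. Of the embryo count cells 6 were empty and were read as 0. The authors also deposited tables of their own comparisons, whose columns per the file headers are a mean and a statistic (used as scores), a log2 fold change with its standard error, and a p-value with its adjusted p-value. In the wing disc count table the columns named wt were taken as Halo-Trl, the only genotype left without columns of its own. In the embryo table the columns of the knock-out and GFP-GAF groups were taken as GAF-deGradFP and sfGFP-GAF(N) control. The authors' RNA comparison is not labelled. It was refitted with DESeq2, and 14478 of 14598 fold changes lay within 0.01 of delta-POZ against Halo-Trl.

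Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test (glmQLFit and glmQLFTest) with TMM normalization, all genotypes of an assay in 1 fit and genotype as the only term. RNA genes were filtered with filterByExpr, which left 10359, and loops needed 10 contacts summed over libraries. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05 with no minimum fold. The standard error printed beside a log2 fold change was derived from the test as the size of the log2 fold change divided by the square root of F. Normalised contacts are contacts divided by a library's effective size relative to the arithmetic mean of the libraries, and CPM use the effective library size. Normalizing over loops removes any shift common to all loops, so loop changes are relative to the other loops in the table. Means are given with the SD over libraries. Where a group held at most 3 reads summed over its libraries, a ratio with its 95% counting interval or a lower bound against 3 reads is given. Intervals cover counting error only.

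Before the data were examined, the groups, the tests, the alternatives, 28 gene lists and the rule for naming genes were fixed. The rule takes Trl; per comparison the 10 largest rises and 10 largest falls with adjusted p under 0.05, a mean log2 CPM of at least 1 and every library of one group above the other; and per list up to 4 called members with the smallest p, or up to 2 as values where none was called. For loops it takes up to 10 falls and 5 rises with separated groups, and the 8 loops with the highest mean contacts that name a gene of a fixed list of paralogs. Not all genes that the rule allows are printed. Genes at anchors of reduced loops, genes that differed alike in both deletion lines and genes of the closing section were named after their values were seen. They were recomputed under the same alternatives. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and adjusted over the lists of a comparison; every call of these 28 lists was lost when the correlation was estimated. Of the RNA table's names, 17198 were current symbols and 17809 matched with synonyms in a RefSeq gene table (assembly Release 6 plus ISO1 MT), which was used only for names and neighbours; 9 names in the lists found no match. Genes at loop anchors are those the authors' loop lists name, of which 159 of 164 wing disc names matched the RNA table.

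Embryo and wing disc loops were taken as shared where both anchors overlapped within 5 kb. Chance values of comparisons that share Halo-Trl were simulated 40 times for RNA and 100 times for loops, and those of loop comparisons that share delta-POZ 100 times. Permutation tests used 100000 resamples. The edgeR test was tried on simulated counts with known changes (200 genes in 3 simulations, 20 loops in 10 simulations). Alternatives were other normalizations, DESeq2 1.42.0, other filters and thresholds, a replicate block, leaving out each replicate in turn, and, chosen after the data were seen, leaving out 3 libraries together, crossed replicate numbers and summing embryo controls 2 and 3. Tests of GAGAG motifs at anchors and of transcription start sites near anchors were not run, since no genome or annotation of the files' build was used here. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for joins and figures.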

Results

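The series examined how chromatin contacts and gene expression respond when GAGA-associated factor (GAF) is depleted or truncated in Drosophila melanogaster. GAF, the product of Trithorax-like (Trl), binds GAGAG motifs through a zinc finger, and its POZ domain joins GAF molecules to one another. Of the 30 samples, 8 were embryo contact maps, 6 were wing disc contact maps, 9 were wing disc RNA-seq libraries, and 7 were CUT&Tag samples that were not analysed here. The embryo maps compared 4 libraries of embryos in which GAF protein was depleted by deGradFP (labelled GAF(deGradFP) and written GAF-deGradFP here) with 4 control libraries carrying sfGFP-tagged GAF (labelled sfGFP-GAF(N) control), all aged 2 to 2.5 h. The wing disc maps (90 discs per replicate) and RNA-seq libraries (30 discs per replicate) came from wandering late larvae. They compared Halo-tagged full-length GAF (Halo-Trl) with Halo-tagged GAF lacking the POZ domain (delta-POZ) or the Q domain (delta-Q), with n = 2 maps and n = 3 RNA libraries per genotype.

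Embryo libraries held 1715 to 7347 contacts summed over 186 loops, a 4.28-fold range, and wing disc libraries held 23944 to 31995 contacts over 209 loops. RNA libraries held 57673928 to 85575887 reads in genes, of which mitochondrial genes took 15.2% to 31.2%. No 2 libraries were identical. Embryo controls 2 and 3 did not differ beyond the counting noise (chi-square per degree of freedom 1.02, p = 0.403), while the other control pairs gave p from 1.38e-09 to 0.0442. Control 3 was the shallowest library, with 1715 contacts. Thinned to that depth, control 1 could not be told from control 2 in 72 of 100 thinnings, so that agreement was not peculiar to controls 2 and 3 and both were kept as separate samples. Control 4 differed from the others at that depth in most thinnings. Among the depleted libraries, GAF-deGradFP 4 stood apart, with a chi-square per degree of freedom of 2.64 to 3.83 against each of the others. The remaining depleted pairs gave 1.35 to 1.45. The embryo labels do not say whether replicates were separate collections, so the embryo p-values measure the spread between these samples, which may be technical.

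To ask which loops depend on GAF protein in early embryos, contacts at the 186 loops were compared between GAF-deGradFP and control libraries. The loop between CG7560 and charybde (chrb), an inhibitor of TOR signalling, lost the largest share of its contacts, which fell by 75.2%. Normalised contacts were 6.82 ± 2.85 (SD, n = 4) after depletion and 28.3 ± 3.15 (n = 4) in controls, a log2 fold change of -2.01 (SE 0.34, edgeR adjusted p = 1.87e-04). Its anchors lie on chromosome 3L at 11427801 to 11429400 and 11486601 to 11488200, 58.8 kb apart (build not given in the sources used here). The loop between smal and Ddr, neighbouring genes for discoidin-domain receptors, fell by 65.2% (10.8 ± 6.95 against 28.7 ± 6.86, log2 -1.52, SE 0.33, adjusted p = 0.00589; chromosome 2L, 6178201 to 6179800 and 6251801 to 6253400). Its highest depleted library, at 20, lay above its lowest control, at 19.5, so it is named here after its values were seen.

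Contacts also fell at a loop joining upd2 and upd1, which encode JAK/STAT ligands (21.7 ± 3.18 against 40.4 ± 13.8, log2 -0.89, SE 0.25, adjusted p = 0.0477; chromosome X, 18243001 to 18244600 and 18311801 to 18313400). The loop labelled TfAP-2RA and TfAP-2RB, 2 labels read here as the single gene TfAP-2, fell by 42.8% (39.6 ± 1.16 against 70.2 ± 11.1, log2 -0.81, SE 0.20, adjusted p = 0.0237). These anchors lie 13.6 kb apart on chromosome 3L (21584201 to 21585800 and 21597801 to 21599400). A single loop rose, by 87.2%, from 20.3 ± 4.48 to 39.2 ± 3.26 normalised contacts (log2 0.90, SE 0.23, adjusted p = 0.0237). Its anchors on chromosome 2L, 21898801 to 21900400 and 22023601 to 22025200, carry no gene label in the embryo list, and the loop at the matching place in the wing disc list is labelled tiptop (tio). The 8 loops of the fixed paralog list with the highest mean contacts, among them those of H15/mid, kni/knrl, inv/en and drm/odd, were not called, with log2 fold changes of -0.09 to 0.59 and adjusted p of 0.138 to 0.95. The highest was that of slp1/slp2 (log2 0.59, SE 0.22, unadjusted p = 0.0115, edgeR adjusted p = 0.138). In all, 4 loops fell and 1 rose of 186, with 29 at an unadjusted p under 0.05, where 9.3 are the chance number.

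At this depth the test found 44% of simulated changes of log2 -1 and 5% of those of -0.5, so smaller changes were mostly not detectable. DESeq2 called 3 loops. Without single libraries the count ranged from 1 (without GAF-deGradFP 1 or control 2) to 16 (without GAF-deGradFP 4, with 12 lower and 4 higher). It was 2 without GAF-deGradFP 2, GAF-deGradFP 3 or control 3 and 3 without control 4. GAF-deGradFP 4 was the depleted library that differed most from the others, so the number of falls depends strongly on it. The chrb loop was called in each of the 16 alternatives that gave a value, with adjusted p up to 0.00634. The smal/Ddr loop lost its call without GAF-deGradFP 1, control 2 or control 4 (adjusted p up to 0.105 over all alternatives). Each of the loops of upd2/upd1, TfAP-2RA/TfAP-2RB and the rising loop lost its call in 9 alternatives, including without GAF-deGradFP 1, 2 or 3 or control 2 or 3 (adjusted p up to 0.379, 0.105 and 0.151), and the latter pair also without control 1 and without control 4, respectively. With controls 2 and 3 summed as 1 sample, a choice made after the data were seen, 5 loops were called, of which 4 were shared and upd2/upd1 was not. The authors' deposited table calls 3 embryo loops lower and 0 higher.

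To ask which wing disc loops differ when GAF lacks the POZ domain, delta-POZ was compared with Halo-Trl over 209 loops. Since no library separates line from deletion, line background cannot be told apart from the deletion in any comparison of these genotypes. Contacts fell at 9 loops and rose at 0, with 22 at an unadjusted p under 0.05 (5 higher and 17 lower) against 10.5 by chance. DESeq2 called 8 lower and 0 higher. The chrb loop again fell most, by 65.9%, from 125 ± 3.8 to 42.5 ± 0.226 normalised contacts (SD, n = 2 per genotype; log2 -1.55, SE 0.21, edgeR adjusted p = 6.63e-11; chromosome 3L, 11426901 to 11431900 and 11484501 to 11489500). A longer loop of 240 kb from chrb to its paralog scylla (scyl) on the same arm, 11245301 to 11250300 and 11485301 to 11490300, fell by 57.9% (35 ± 1.44 against 82.8 ± 6.53, log2 -1.25, SE 0.23, adjusted p = 5.66e-06).

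Paired transcription factor genes were among the loops that fell. The loop of escargot (esg) and worniu (wor), which encode Snail-family factors, dropped by 60.5% (37.9 ± 3.2 against 95.6 ± 5.75, log2 -1.34, adjusted p = 3.69e-07; chromosome 2L, 15330101 to 15335100 and 15423701 to 15428700). Contacts between bab1 and bab2, BTB-domain genes that pattern the limbs, fell by 51.4% (63.1 ± 5.48 against 130 ± 17.2, log2 -1.04, SE 0.19, adjusted p = 5.66e-06; chromosome 3L, 1099701 to 1104700 and 1174901 to 1179900). The smal/Ddr loop (chromosome 2L, 6177101 to 6182100 and 6249901 to 6254900) fell by 55.3%, from 74.5 ± 10.9 to 32.7 ± 10.3 (adjusted p = 1.83e-05). Loops labelled kek1 (log2 -0.98, adjusted p = 1.14e-05), lozenge (lz; -0.84, 5.56e-04), CG14372 (-0.73, 2.76e-04) and dnr1 (-0.55, 0.0291) made up the rest.

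Loops of several other paralogous pairs were not called. Contacts between spalt major (salm) and spalt-related (salr), which pattern the wing, were 216 ± 1.35 in delta-POZ and 196 ± 33.7 in Halo-Trl (log2 0.13, SE 0.16, adjusted p = 0.808). The 8 loops with the highest mean contacts that name a gene of the paralog list, including those of H15/mid, kni/knrl, Doc1/Doc2 and B-H1/B-H2 and 2 that name a single gene (H15 and Scr), had log2 fold changes of -0.03 to 0.33 and adjusted p of 0.532 to 0.946. Counts ranged from 7 to 10 over the alternatives, and 94% of simulated changes of log2 -1 but 32% of those of -0.5 were found. The lz loop lost its call without Halo-Trl 2 or delta-POZ 1 (adjusted p up to 0.145), the CG14372 loop without Halo-Trl 1 or delta-POZ 2 (up to 0.107), and the dnr1 loop in 7 of 14 alternatives, including without each of the 4 libraries (up to 0.495). Leaving out 1 of 2 libraries assumes that the lone sample varies like the other groups. The authors' deposited table calls 8 loops lower and 0 higher in this comparison.

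Deletion of the Q domain gave no detectable loop change in wing discs. Against Halo-Trl, edgeR called 0 of 209 loops, with 4 at an unadjusted p under 0.05 and a smallest adjusted p of 0.369, and DESeq2 called 0. The authors' deposited table also calls 0. In delta-Q the chrb loop held 136 ± 22.8 normalised contacts (log2 0.12, SE 0.18), bab1/bab2 129 ± 9.25 (log2 -0.02), smal/Ddr 59.5 ± 3.86 (log2 -0.33) and esg/wor 73.3 ± 11.5 (log2 -0.38, SE 0.21), each with adjusted p = 0.988. In simulated data, 86% of changes of log2 -1 and 27% of those of -0.5 were found.

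A direct comparison of both deletions separated them. Contacts at 9 loops were higher in delta-Q than in delta-POZ and 0 were lower, with 26 at an unadjusted p under 0.05. The chrb loop differed by log2 1.67 (SE 0.21, edgeR adjusted p = 3.49e-12), scyl/chrb by 1.27 (SE 0.24, 1.80e-05), lz by 1.03 (SE 0.20, 2.29e-05), bab1/bab2 by 1.02 (SE 0.20, 2.71e-05) and esg/wor by 0.96 (SE 0.24, 0.0029). Named after their values were seen, the remaining 4 loops were those of CG14372, kek1, smal/Ddr and Hr3/Hdc, so that 8 of the 9 loops that fell in delta-POZ were higher in delta-Q. Both comparisons use the delta-POZ libraries, so part of this overlap may come from the shared libraries. Against them, 100 simulations of unchanged groups each gave 0 such loops, and independent lists would share 0.388. Neither value covers loops that truly fell in delta-POZ, so neither shows how large that part is. The dnr1 loop was not called (log2 0.50, adjusted p = 0.0819). DESeq2 called 5 loops, and the esg/wor call was lost with DESeq2 and without delta-POZ 2 or delta-Q 1 (adjusted p up to 0.215 over 13 alternatives).

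Embryo and wing disc results were then set side by side at the 61 loops whose anchors overlapped within 5 kb. The chrb and smal/Ddr loops fell both after GAF depletion in embryos and in delta-POZ discs. They were the 2 shared loops that fell in embryos, and 5 shared loops fell in wing discs (Fisher's exact test, two-sided p = 0.00546). The embryo call of smal/Ddr was lost without GAF-deGradFP 1, control 2 or control 4, which left 1 loop that fell in both (p = 0.082 in each case by the same exact test), while 4 fell in both without GAF-deGradFP 4 (exact p = 4.72e-05). Other shared loops that fell in wing discs, scyl/chrb, bab1/bab2 and CG14372, had embryo log2 fold changes of -0.87 (adjusted p = 0.149), -0.71 (0.311) and 0.15 and were not called there. Across the shared loops, which are not independent replicates, fold changes correlated with Spearman's rho of 0.35 (permutation p = 0.0067) and Pearson's r of 0.65 (p = 1.00e-05, the smallest that 100000 permutations can give), and rho was 0.28 over the 55 loops called in neither tissue. Loops that fell in delta-POZ discs were long, with a median anchor distance of 72.8 kb against 30.4 kb for the other loops (two-sided permutation p = 0.01). For the embryo loops that fell the medians were 63.8 and 34.2 kb (permutation p = 0.11).

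**Figure D1:**
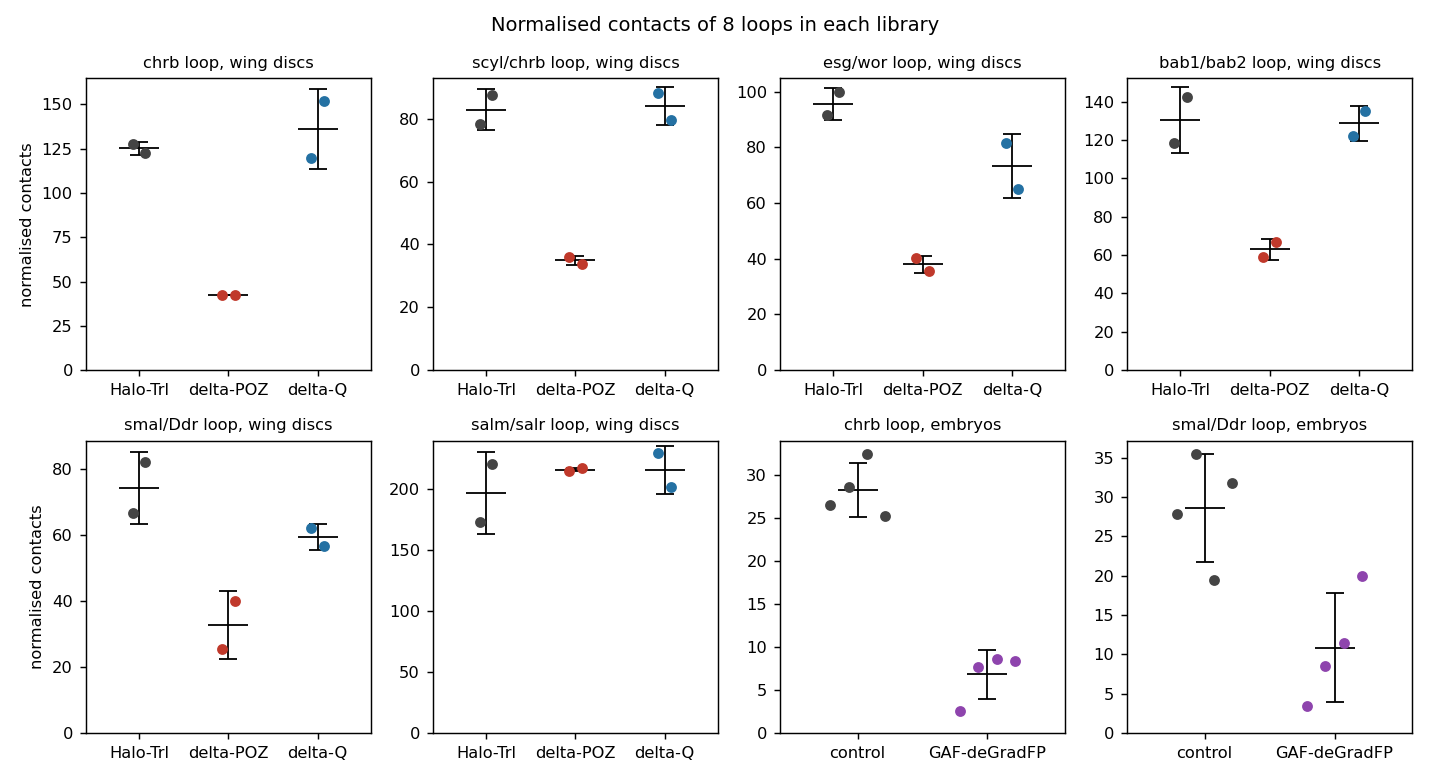
Normalised contacts (vertical axis, from 0) at 6 wing disc loops and 2 embryo loops, by genotype; points are libraries, the horizontal line is the group mean and bars are the SD. The chrb loop stood at 125 in Halo-Trl, 42.5 in delta-POZ and 136 in delta-Q discs, while the salm/salr loop did not differ between delta-POZ and Halo-Trl beyond its error.

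RNA from the same 3 wing disc genotypes was compared to find the genes that differ in each deletion line. As for the loops, line background cannot be told apart from the deletion in any of these comparisons. Trl itself was measured at 51.34, 49.75 and 41.75 CPM (counts scaled to library size) in Halo-Trl, 78.39, 67.65 and 61.04 in delta-POZ and 56.62, 60.3 and 63.97 in delta-Q. It was higher in delta-POZ (log2 0.54, SE 0.12, edgeR adjusted p = 0.0234), a call lost in 7 of 16 alternatives, including without Halo-Trl 2 or 3 or delta-POZ 1 or 2 (adjusted p up to 0.104). The difference in delta-Q was 0.34 (adjusted p = 0.447). Counts over a whole gene do not check a domain deletion, and Trl overlaps Tsen34 and CG42507, whose reads cannot be told apart if counting ignored strand.

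In delta-POZ, 511 genes rose and 539 fell of 10359 tested. The gene chrb, whose loop lost the largest share of its contacts, fell from 931 ± 67.7 to 397 ± 48.3 CPM (SD, n = 3, log2 -1.23, SE 0.15, edgeR adjusted p = 0.00103). Among the largest falls, the mitochondrial aspartate-glutamate carrier aralar1 fell from 19.8 ± 1.2 to 0.338 ± 0.265 CPM (log2 -5.88, SE 0.54, adjusted p = 2.41e-04), the amino acid transporter JhI-21 from 29 ± 3.04 to 0.828 ± 0.307 (log2 -5.13, adjusted p = 3.23e-05; overlaps PLCXD), and the pyruvate carboxylase gene PCB from 35.7 ± 4.05 to 1.67 ± 1.64 (log2 -4.43, adjusted p = 0.00261; overlaps an antisense RNA). The largest separated falls also included CG18547 (log2 -7.11, SE 0.33, adjusted p = 3.44e-06) and hng3 (-3.41; overlaps emc). Among the largest rises, ppk13, a DEG/ENaC channel subunit, went from 0.105 ± 0.112 to 40.4 ± 3.84 CPM (log2 8.50, SE 0.50, adjusted p = 2.23e-05) and CG33509 from 0.0827 ± 0.0745 to 18.7 ± 1.62 (log2 7.86, adjusted p = 9.05e-05). Oseg5, an intraflagellar transport gene, was at 8.09 ± 1.5 CPM against a Halo-Trl group with 2 reads in all, a ratio of 844 (95% counting interval 233 to 6980, covering counting error only; overlaps CG31674).

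Of the delta-POZ calls, 99.6% had all libraries of one genotype above the other, as did 33% of all genes tested, where chance gives 10%. DESeq2 called 1719 genes (915 higher, 804 lower), and 508 of the edgeR calls were at least 2-fold. The count was 487 without Halo-Trl 2, 411 without Halo-Trl 3, 663 without delta-POZ 2 and 689 without delta-POZ 3. In simulations, 44% of falls and 34.7% of rises of log2 1 in size were found, with 2.2% false among the simulated calls. Simulated genes varied independently of one another. Shifts that many genes share in 1 library were not covered, so the false share among the real calls is not known from this. Reads of overlapping genes could not be assigned by strand, since the counting is not stated to use it. The authors' deposited RNA table, whose comparison is not labelled, calls 914 genes higher and 804 lower, and 99.2% of its fold changes lay within 0.01 of a DESeq2 fit of delta-POZ against Halo-Trl.

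Growth-related groups were lower in delta-POZ. Of 86 ribosomal protein genes, 24 fell and 0 rose (36 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.52e-13, adjusted p = 0.18 with an estimated correlation), with RpL24 at 54.1 ± 8.2 against 111 ± 12.1 CPM (log2 -1.03, SE 0.14; overlaps CG7099) and RpL17 at log2 -0.60 (SE 0.09; overlaps snoRNA genes). The list of 30 cell cycle genes held 6 that fell and 2 that rose (12 and 2 adjusted over the list alone; camera adjusted p = 3.35e-04, or adjusted p = 0.18 with an estimated correlation). Mcm3, a subunit of the replicative helicase, fell to 32.4 ± 2.65 from 69.3 ± 7.4 CPM (log2 -1.10, SE 0.13, adjusted p = 8.66e-04; overlaps CG3309), and the ribonucleotide reductase gene RnrL changed by log2 -0.59 (SE 0.09).

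Stress and cuticle groups were higher. Of 23 JNK, stress and regeneration genes, 6 rose and 0 fell (7 adjusted over the list alone; camera adjusted p = 0.00237, or adjusted p = 0.18 with an estimated correlation), including the stress-response factor Xrp1 at 156 ± 19 against 85.7 ± 2.47 CPM (log2 0.86, SE 0.16, adjusted p = 0.00806). Cuticle genes numbered 6 higher and 0 lower of 41 (8 adjusted over the list alone; camera adjusted p = 0.00445, or adjusted p = 0.18 with an estimated correlation), and the list call was lost without delta-POZ 2 (adjusted p = 0.0816). Cpr100A rose from 0.626 ± 0.368 to 21.9 ± 3.52 CPM (log2 5.11, SE 0.49, adjusted p = 2.95e-04) and TwdlT from 1.19 ± 0.33 to 14.3 ± 3.95 (log2 3.58; overlaps RYa-R). Of 9 segmentation genes, 2 rose (4 adjusted over the list alone; camera adjusted p = 0.0343, or adjusted p = 0.315 with an estimated correlation), a list call lost without delta-POZ 2 (0.0828) and without delta-POZ 2, Halo-Trl 1 and delta-Q 3 together (0.0561). Hemocyte markers, expressed in blood cells, gave 6 higher and 1 lower of 16 (8 and 2 adjusted over the list alone). As a list they gave camera adjusted p = 0.00438, or adjusted p = 0.589 with an estimated correlation. Without delta-POZ 3 the camera adjusted p was 0.0501. Their median lay at -0.05, -1.02 and -0.83 log2 units from the mean of the 9 libraries in Halo-Trl 1 to 3. In delta-POZ 1 to 3 it lay at -0.3, 0.96 and 0.87, so the genotypes overlapped and single libraries differed. The scavenger receptor gene crq rose to 135 ± 29.2 from 67.6 ± 5.95 CPM (log2 1.00; overlaps ex), while the crystal cell gene PPO2 fell from 55.7 ± 11.8 to 5.81 ± 4.14 (log2 -3.26, SE 0.62, adjusted p = 0.0103).

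Markers of other tissues differed between single libraries as well as between genotypes. Of 14 neuronal markers, 3 rose in delta-POZ (10 adjusted over the list alone; camera adjusted p = 0.00438, or adjusted p = 0.609 with an estimated correlation), and the list gave adjusted p = 0.468 without delta-POZ 2 and 0.592 without delta-POZ 2, Halo-Trl 1 and delta-Q 3 together. In that library their median lay 4.63 log2 units above the mean of the 9 libraries, against -1.35 to 0.13 in the others, and the median of 16 muscle markers lay 2.93 above it. Several of the largest rises, including CanB (ratio 553, 95% counting interval 189 to 2680) and VAChT, the vesicular acetylcholine transporter gene, had an SD above their mean. Both lost their call without delta-POZ 2 and also without Halo-Trl 1, 2 or 3 (adjusted p up to 0.484 for CanB and 0.207 for VAChT, which overlaps ChAT). The microtubule-associated protein gene futsch was called in all 16 alternatives (58.4 ± 17.5 against 17.9 ± 0.393 CPM, log2 1.71, SE 0.26, adjusted p = 0.00322; overlaps Gr2a). Fat body markers were highest in Halo-Trl 1 (median 4.5 above the mean), delta-Q 3 (3.87) and delta-Q 2 (1.42). Without delta-POZ 2, Halo-Trl 1 and delta-Q 3, left out together after the data were seen, 706 genes were called in delta-POZ (363 higher, 343 lower), of which 568 were shared.

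The remaining 21 of 28 lists were not called in delta-POZ, with camera adjusted p of 0.0537 to 0.966. Some of these were called without 1 library: Enhancer of split genes without Halo-Trl 1, 2 or 3 or delta-POZ 3 (lowest 0.00575), muscle markers without Halo-Trl 2 or 3 or delta-POZ 1 or 3 (0.00293), tracheal markers without Halo-Trl 2 or 3 or delta-POZ 2 (0.0157) and also with the replicate block (0.0473), Osiris genes without Halo-Trl 2 or 3 (0.0355), Trithorax group genes without Halo-Trl 1 or delta-POZ 1 (0.031), ecdysone genes without Halo-Trl 2 (0.0435) and fat body markers, then higher, without Halo-Trl 1 (0.0407) and also without the 3 libraries together (0.00174). Among 55 wing patterning genes 1 fell, the Iroquois gene araucan (ara; log2 -0.39, adjusted p = 0.0319, lost in 10 of 16 alternatives with adjusted p up to 0.185, including without any 1 of the 6 libraries), and 0 passed adjusted over the list alone. Of 24 ecdysone genes 3 fell (5 lower and 1 higher adjusted over the list alone), among them the nuclear receptor gene Hr4, at 27.7 ± 9.18 against 99.4 ± 21.1 CPM (log2 -1.85, SE 0.27, adjusted p = 0.00267; overlaps PIG-K and CR46447). Heat shock genes included, in both adjustments (over all genes and adjusted over the list alone), 1 rise, Hsp67Ba (log2 1.11; overlaps an antisense RNA), and 1 fall, the co-chaperone starvin (stv), from 17.1 ± 3.42 to 3.12 ± 0.089 CPM (log2 -2.45, SE 0.18, adjusted p = 9.05e-05). Detoxification genes numbered 3 higher and 8 lower of 93 (4 and 8 adjusted over the list alone), with GstE12 at log2 -1.04 (SE 0.12; overlaps CG3894). The paralogous zinc finger genes elB and noc moved in opposite directions, elB from 47.7 ± 6.2 to 12.7 ± 0.157 CPM (log2 -1.91, SE 0.16, adjusted p = 1.84e-04) and noc from 122 ± 5.52 to 255 ± 37.8 (log2 1.06, SE 0.13, adjusted p = 0.00106).

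**Figure D2:**
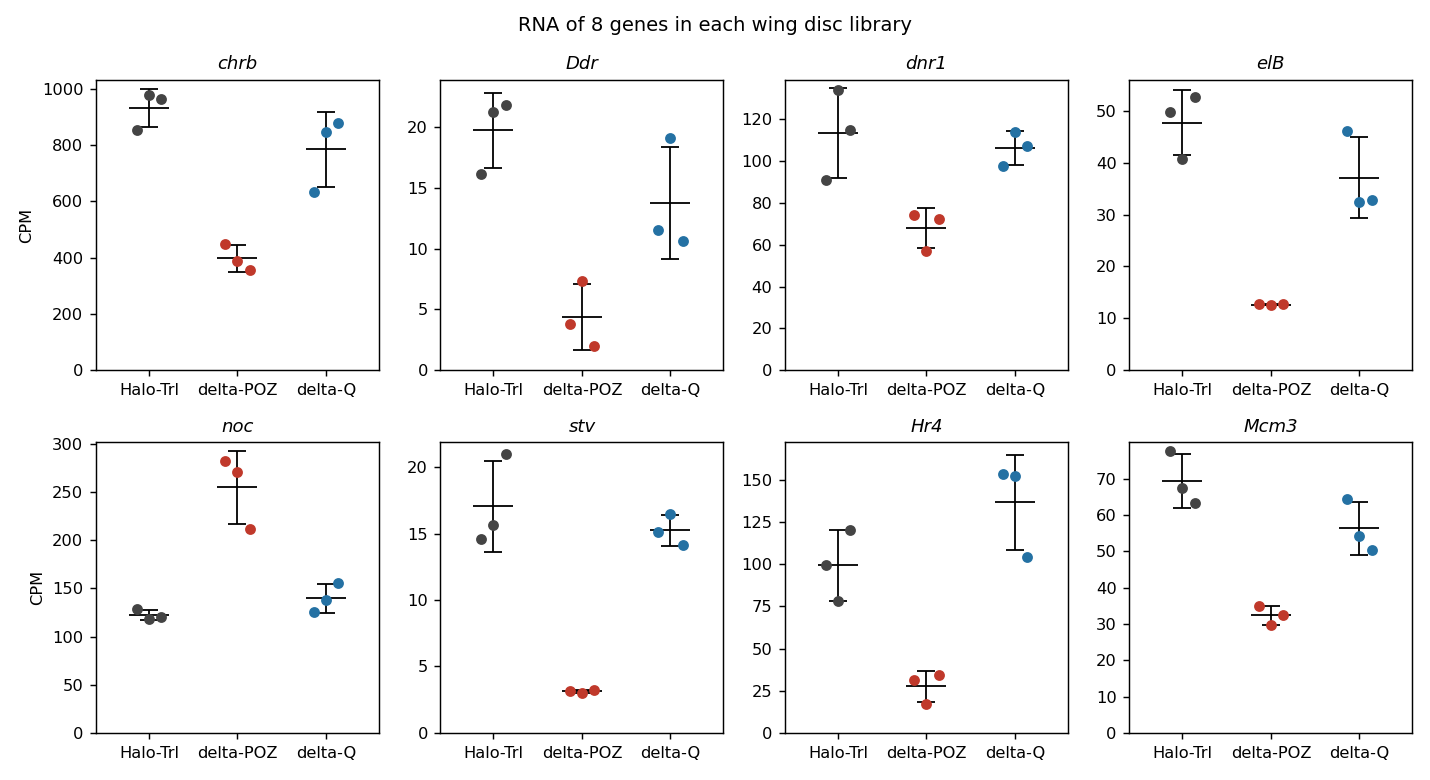
RNA of 8 genes in each wing disc library, in CPM on an axis from 0, by genotype; points are libraries, the horizontal line is the mean and bars are the SD (n = 3). The chrb mean was 931 in Halo-Trl, 397 in delta-POZ and 785 in delta-Q.

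**Figure D3:**
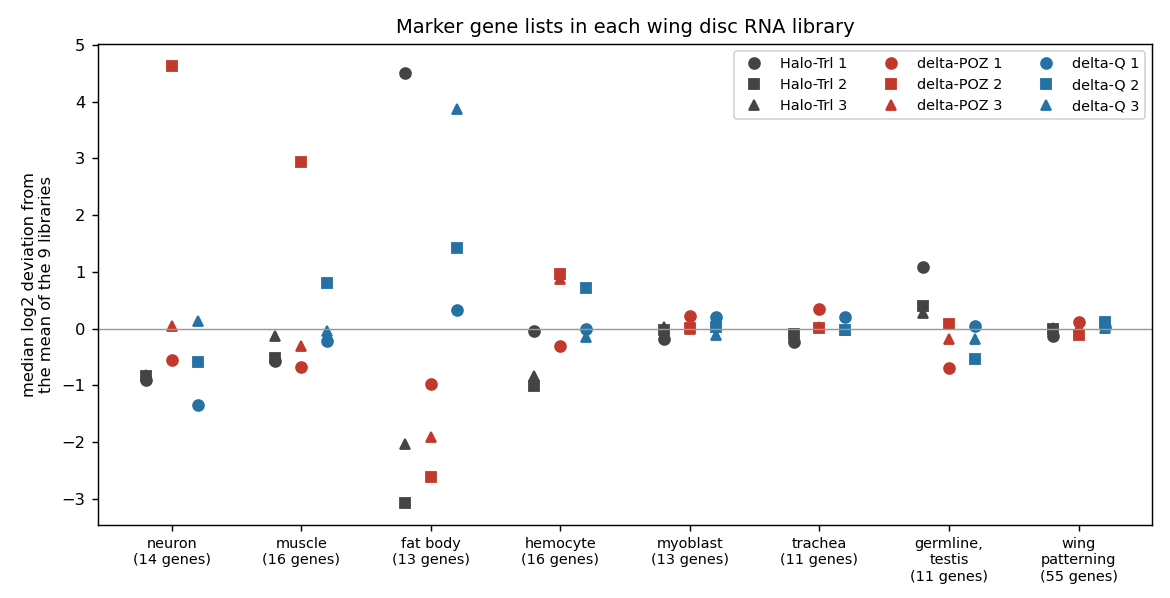
Median log2 deviation of 8 marker gene lists (vertical axis) from the mean of the 9 RNA libraries, one point per library. Neuronal markers stood at 4.63 and muscle markers at 2.93 in delta-POZ 2, fat body markers at 4.5 in Halo-Trl 1, and wing patterning genes between -0.13 and 0.12 in all libraries.

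Fewer genes were called in delta-Q, where 41 rose and 27 fell of 10359. Of these, 42 moved in the same direction in delta-POZ, where line background and deletion cannot be told apart. The chloride channel gene tweety (tty) rose from 7.36 ± 1.56 to 285 ± 23.6 CPM (log2 5.27, SE 0.20, edgeR adjusted p = 1.28e-06). The channel gene ppk13 reached 38.5 ± 8.05 CPM (log2 8.43, SE 0.50, adjusted p = 5.94e-05), and Oseg5 exceeded its near-silent Halo-Trl level by a ratio of 657 (95% counting interval 182 to 5430; overlaps CG31674). The spliceosomal gene sans fille (snf) fell from 43 ± 1.07 to 10.4 ± 0.93 CPM (log2 -2.05, SE 0.14, adjusted p = 9.72e-05), JhI-21 to 2.62 ± 0.726 (log2 -3.46, adjusted p = 4.05e-04; overlaps PLCXD), and the zinc finger gene tio from 93.2 ± 8.46 to 30 ± 1.41 (log2 -1.63, SE 0.11, adjusted p = 9.72e-05; overlaps a long non-coding RNA). SoYb, a Tudor-domain gene of the piRNA pathway that overlaps CG31875, fell to 5.25 ± 1.42 from 28.2 ± 1.14 CPM (log2 -2.42, SE 0.26, adjusted p = 0.00181), and bou, needed for septate junctions, fell to 12.5 ± 2.08 from 44.1 ± 2.39 (log2 -1.82, SE 0.15; overlaps ogre). The chrb gene was at 785 ± 133 CPM (log2 -0.25, SE 0.15, adjusted p = 0.794).

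All 68 delta-Q calls separated the genotypes, as did 13.1% of all genes, where chance gives 10%. DESeq2 called 248 genes, and 810 genes had an unadjusted p under 0.05. The count was 24 without Halo-Trl 2, 21 without Halo-Trl 3, 23 without delta-Q 2 and 40 without delta-Q 3, and it was 45 with replicate numbers as a block. Without delta-POZ 2, Halo-Trl 1 and delta-Q 3, which held most RNA of other tissues, it was 107, of which 46 were shared.

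Of the 28 gene lists, 2 were called in delta-Q. Germline and testis markers were lower as a list, with 1 of 11 passing on its own and 1 adjusted over the list alone (camera adjusted p = 0.0229, or adjusted p = 0.649 with an estimated correlation). That member was the piRNA gene AGO3 (log2 -0.80, adjusted p = 0.0465, lost in 12 of 16 alternatives, including without any 1 of the 6 libraries, up to 0.255). The list call was lost without Halo-Trl 1 (adjusted p = 0.22), delta-Q 2 (0.0528) or delta-Q 3 (0.094) and without the 3 libraries with most RNA of other tissues (0.296), and the median of these markers was highest in Halo-Trl 1, at 1.08 above the mean of the libraries. Hemocyte markers were higher as a list with 0 of 16 members passing in either adjustment (camera adjusted p = 4.58e-04, or adjusted p = 0.933 with an estimated correlation). Without delta-Q 2 the camera adjusted p was 0.0729. The median of these markers was -0.15 in delta-Q 3 and -0.05 in Halo-Trl 1, so the genotypes overlapped. The other 26 lists gave adjusted p of 0.0556 to 0.955, and 0 of 55 wing patterning genes passed. Of these, fat body markers were called higher in 6 of 11 alternatives: with the replicate block (adjusted p = 0.00993), with RLE or upper quartile normalization, without Halo-Trl 1 (7.00e-14), without delta-Q 1 (0.00256) and without the 3 libraries (1.65e-25). Ribosomal proteins were called lower in 4, without Halo-Trl 1 (0.0369), without the 3 libraries (0.0279) and with either normalization. Muscle markers were called without delta-Q 1 (0.0116) and with upper quartile normalization, and Enhancer of split genes without delta-Q 1 (0.0333).

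Set directly against delta-POZ, delta-Q discs had 316 genes higher and 161 lower. Among them, chrb was higher in delta-Q by log2 0.98 (SE 0.15, edgeR adjusted p = 0.00554), aralar1 by 5.37 (13.9 ± 5.62 against 0.338 ± 0.265 CPM, adjusted p = 6.47e-04), CG18547 by 5.67 (SE 0.31, adjusted p = 5.85e-05) and stv by 2.29 (15.2 ± 1.16 against 3.12 ± 0.089 CPM, adjusted p = 1.87e-04). The crystal cell gene PPO2 was higher by 4.15 (SE 0.64, adjusted p = 0.00636). Lower in delta-Q were zye (0.943 ± 0.145 against 87.7 ± 49.8 CPM, log2 -6.54, SE 0.61, adjusted p = 5.47e-04), yellow-h (2.87 ± 0.428 against 36.5 ± 7.14 CPM, log2 -3.67, SE 0.24, adjusted p = 1.72e-04; overlaps an antisense RNA) and Cpr100A (log2 -4.14, SE 0.46, adjusted p = 0.0011). The elB and noc genes differed in opposite directions again, at 1.55 (SE 0.16) and -0.87 (SE 0.13). All 477 calls separated the genotypes, as did 24.2% of all genes, where chance gives 10%.

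DESeq2 called 1071 genes between the deletions, 555 higher and 516 lower, so 51.8% of its calls were higher against 66.2% of edgeR's. The count was 313, 268 and 237 without delta-POZ 1, 2 and 3, 281 and 268 without delta-Q 1 and 2, and 263 with only these 2 genotypes in the fit. Leaving out the 3 libraries with most RNA of other tissues gave 312, of which 256 were shared.

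Ribosomal protein genes were higher in delta-Q than in delta-POZ, with 13 of 86 passing and 0 lower (32 adjusted over the list alone; camera adjusted p = 1.27e-11, or adjusted p = 0.314 with an estimated correlation). RpL7A stood at 456 ± 37.6 against 245 ± 28.1 CPM (log2 0.90, SE 0.11, adjusted p = 0.00206; overlaps a snoRNA). Of 30 cell cycle genes 4 were higher, including Mcm3 (log2 0.80, SE 0.13; 11 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00175, or adjusted p = 0.316 with an estimated correlation; 0.149 without the 3 libraries). Ecdysone genes gave 3 higher of 24, led by Hr4 (137 ± 28.1 against 27.7 ± 9.18 CPM, log2 2.31, SE 0.27, adjusted p = 0.00151; 8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0271, or adjusted p = 0.316 with an estimated correlation; 0.0695 without delta-POZ 2 and 0.0913 without delta-Q 2). The 23 Trithorax group genes were higher as a list with 0 passing and 4 adjusted over the list alone (camera adjusted p = 0.0057, or adjusted p = 0.588 with an estimated correlation; 0.0955 without delta-POZ 2 and 0.062 without delta-Q 1).

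JNK, stress and regeneration genes were lower in delta-Q, 3 of 23 in both adjustments (over all genes and adjusted over the list alone; camera adjusted p = 0.00218, or adjusted p = 0.218 with an estimated correlation), with Gadd45 at 12 ± 2.2 against 23.9 ± 2.03 CPM (log2 -0.99, SE 0.17, adjusted p = 0.0108; 0.0515 without delta-POZ 3). Cuticle genes gave 3 lower of 41, likewise 3 adjusted over the list alone (camera adjusted p = 0.0415, or adjusted p = 0.329 with an estimated correlation), a list call lost in 8 of 11 alternatives, including without the 3 libraries (0.117), delta-POZ 2 (0.264), delta-Q 1 (0.145), delta-Q 2 (0.109) or delta-Q 3 (0.0561). Neuronal markers were lower with 0 of 14 passing and 8 adjusted over the list alone (camera adjusted p = 0.00218, or adjusted p = 0.588 with an estimated correlation; 0.149 without the 3 libraries and 0.814 without delta-POZ 2, the library in which these markers were highest). Fat body markers were higher with 0 of 13 passing and 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0415, or adjusted p = 0.588 with an estimated correlation). That call was lost without any 1 of the delta-POZ libraries (0.0897, 0.102 and 0.0548), delta-Q 2 (0.0591) or delta-Q 3 (0.0912). The other 20 lists gave adjusted p of 0.195 to 0.799, and hemocyte markers among them gave 0.00788 without delta-POZ 1.

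Some genes differed alike from Halo-Trl in both deletion lines. No library separates line from deletion, so a difference in background between the lines cannot be told apart from a shared effect of the deletions. Of 43 genes called in each against Halo-Trl, 30 rose in both, 12 fell in both and 1 moved in opposite directions, where independent lists would share 2.02 rises and 1.4 falls. Both comparisons use the Halo-Trl libraries, and 40 simulations of unchanged groups against them gave at most 1 gene called alike. The tty gene was higher by log2 5.10 in delta-POZ and 5.27 in delta-Q, ppk13 by 8.50 and 8.43, and CG33509 by 7.86 and 7.78. JhI-21 was lower by -5.13 and -3.46, tio by -2.87 and -1.63, and CG18547 by -7.11 and -1.44. The delta-Q call of CG18547 was lost without any 1 of the 6 libraries (adjusted p up to 0.176), while the other genes named here were called in all 16 alternatives of both comparisons. Across genes, which are not independent replicates, fold changes correlated with Pearson's r of 0.60 and Spearman's rho of 0.48, against 0.49 and 0.44 in simulation, and their covariance was 0.925 against 0.332. With 3 control libraries no split into groups of 2 was possible, so part of the excess may come from the shared controls. The count of shared genes was 11 without Halo-Trl 2 or Halo-Trl 3, 12 without delta-Q 2, 23 without delta-Q 3, 25 without delta-POZ 3 and 66 without the 3 libraries with most RNA of other tissues. Over the 209 wing disc loops the covariance of the fold changes was 0.0176 against 0.0179 in simulation.

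To ask whether genes at loops changed with their loops, RNA was read out at the genes that the authors' loop list names at anchors. At the loops that fell in delta-POZ discs 12 such genes were tested, and 3 were lower in delta-POZ: chrb, dnr1 (68 ± 9.53 against 114 ± 21.6 CPM, log2 -0.74, SE 0.15, edgeR adjusted p = 0.0153) and Ddr (4.38 ± 2.72 against 19.7 ± 3.11 CPM, log2 -2.17, SE 0.42, adjusted p = 0.0113). The dnr1 call was lost without Halo-Trl 2 or 3 (adjusted p up to 0.0655). The other genes at reduced loops did not pass, among them scyl, at the other end of a chrb loop (2100 ± 291 against 1630 ± 157 CPM, log2 0.36, adjusted p = 0.177), smal, at the other end of the Ddr loop (0.21, 0.412), esg (log2 0.30, 0.103), bab1 (0.73, 0.196), bab2 (-0.06, 0.789) and kek1 (0.18, 0.358). These 3 of 12 genes (3 adjusted over the list alone) made 25% against 10.1% of all tested genes (Fisher's exact test, p = 0.114). The 12 include wor (0.107 ± 0.0946 CPM in Halo-Trl) and lz (0.385 ± 0.318). Both were so low that a fall could hardly have been detected. Camera gave a downward direction (p = 0.213, or p = 0.455 with an estimated correlation), opposite in sign to the median of 0.20. Of 145 genes named at any wing disc loop, 11 rose and 9 fell in delta-POZ (11 and 9 adjusted over the list alone; Fisher's exact p = 0.164; camera p = 0.451). Among them elB and noc, labelled at both ends of a single loop, moved in opposite directions, while that loop's contacts were not called (log2 -0.33, adjusted p = 0.62).

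In delta-Q, 0 of the 12 genes and 1 of the 145, tio, differed from Halo-Trl in edgeR's test. Between the deletions, chrb and dnr1 (log2 0.64, adjusted p = 0.0456, lost in 13 of 16 alternatives, including without any 1 of the 6 libraries, up to 0.15) were higher in delta-Q and Ddr was not called (log2 1.65, adjusted p = 0.0531, but called without delta-POZ 2, with a range of 0.00126 to 0.165 over the alternatives), giving 2 of 12 (3 adjusted over the list alone; Fisher's exact p = 0.103). At any loop, 7 genes were higher and 6 lower of 145 (8 and 7 adjusted over the list alone; 9% against 4.6% of all tested genes; Fisher's exact p = 0.0245), while camera gave p = 0.348 (p = 0.6 with an estimated correlation). At the loops that did not fall, 5 genes were higher and 6 lower of 133 (5 and 7 adjusted over the list alone), 8.3% against 4.6%, and the difference did not pass (Fisher's exact p = 0.0565).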

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

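Among the tests of this part, those of neuronal genes in every delta-POZ library, of a stretch of chromosome and of a shared effect of both deletions were chosen after the result was seen.

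In embryos depleted of GAF, the contacts of the CG7560/chrb loop were lowest in library 1, at 2.6 against 7.7, 8.6 and 8.4 in libraries 2 to 4. The gap to the nearest library was 0.862 of the group's range, above the critical value of 0.829 for 4 samples. Of 28 groups tested 1 exceeded it, and chance gives about 1 in 20. All 4 libraries lay below the controls.

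Neuronal transcripts were high in delta-POZ replicate 2. Glial and neuropeptide genes, listed before their values were seen apart from repo, lay above the mean of the other 8 libraries there by a median of 2.51 log2 units over the 18 tested genes (2.75 with repo). Among them were alrm at 10.3 against 0.0597, amon at 15 against 0.165 and Eaat1 at 27.4 against 2.22 CPM. The glial genes Gli (388 against 435) and nrv2 (164 against 294), abundant in all libraries, were not raised. Nor were the less abundant loco (16 against 18.7) and Nplp2 (4.21 against 9.01). Nervous tissue in that library could account for the raised genes, and the labels name no sort that would remove it. The median of 14 neuronal markers over the Halo-Trl mean was also 0.51 and 1.02 in delta-POZ 1 and 3 against 5.76 in delta-POZ 2, although delta-Q 3 reached 0.99. Of the 14, 7 lay above every Halo-Trl library in delta-POZ 1 and 9 in delta-POZ 3. The neuronal gene elav, described below, went the other way in both. A rise in every delta-POZ library thus stays open beside nervous tissue in replicate 2, for part of these genes. Of the 511 rises in delta-POZ, 306 were called without that library, and of the 539 falls, 305.

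In both deletion lines 42 genes differed alike from Halo-Trl. With 1 in the opposite direction the lines shared 43. That count was 11 without Halo-Trl 2 or Halo-Trl 3, 12 without delta-Q 2, 23 without delta-Q 3 and 25 without delta-POZ 3. No simulation of 40 reached 42 genes alike, and the highest count in any of them was 1 gene. That argues against independent chance values of the shared Halo-Trl libraries. Simulated genes varied independently of one another. Shifts that many genes share in 1 library, as the marker lists showed, were therefore not covered and stay open. Of the 42 genes, 6 had another within 10 tested genes on either side, against a median of 2 in random sets (1-sided permutation p = 0.199), which argues against 1 compact stretch of chromosome as the source of most. A wider difference in background between the Halo-Trl line and the deletion lines and a shared effect of both deletions on GAF cannot be told apart, because no library separates line from deletion.

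Of the 10 splits of the 6 RNA libraries, 1 (the real one) gave as many calls in each comparison; the splits are too few for a share under 0.05. The real counts were 1050 for delta-POZ, 68 for delta-Q and 477 between the deletions, and the highest other count was 0 in each. For the embryo loops, 1 of 35 splits (the real one) gave as many as the real 5, the highest other being 1. That share is under 0.05 and is the smallest that 35 splits can give. It argues against a chance split of these libraries but cannot exclude one, and the labels do not say whether they were separate collections.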

How the results depend on the processing

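Tests chosen after the data were seen were the fits without 3 libraries, the crossed numbers, the summed embryo controls, the block for genes at anchors, the ribosome biogenesis list without 4 names, every alternative for the genes shared by both deletions, the single libraries left out for loops that fell in both tissues, and the list alternatives other than the estimated correlation and the block. The remaining alternatives were fixed before the data were examined. Among named genes 3851 of the values under an alternative kept direction and side of the threshold, 444 lost a call, 47 gained one and 0 reversed; among named loops 689 kept it and 44 lost a call; among lists 847 kept it, 47 lost a call, 31 gained one and 2 reversed. The reversed list was the fat body markers in delta-POZ against Halo-Trl, lower at adjusted p = 0.736 and higher without Halo-Trl 1 (0.0407) and without the 3 libraries (0.00174); without single libraries it ranged from 0.0407 to 0.955. At embryo depth 44% of simulated changes of log2 -1 were found.

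Genes changed in delta-POZ numbered 1719 with DESeq2, 508 at 2-fold or more, 357 at adjusted p under 0.01 and 411 to 827 without single libraries. For delta-Q the values were 248, 20 at adjusted p under 0.01, 21 to 57 without single libraries and 107 without the 3 libraries. Between the deletions they were 1071 with DESeq2, 227 at 2-fold or more, 167 at adjusted p under 0.01, 263 with only 2 genotypes, 237 to 364 without single libraries and 312 without the 3. Embryo loops numbered 3 with DESeq2, 0 among loops with a mean of at least 50 contacts (fewer loops tested), 11 at adjusted p under 0.1, 2 under 0.01 and 1 to 16 without single libraries. Wing disc loops between the deletions numbered 5 with DESeq2, 14 at adjusted p under 0.1 and 6 without any single library, and delta-POZ loops 7 to 8 without single libraries. Stricter thresholds lower counts by construction; otherwise the cause was not tested.

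With an estimated correlation 0, 0 and 0 of the 28 lists were called. Without single libraries 5 to 12 lists were called in delta-POZ, 0 to 5 in delta-Q and 3 to 8 between the deletions; delta-Q gave 4 with RLE and 5 with upper quartile normalization, and the third comparison 5 without the 3 libraries. Genes shared by both deletions, 43 in the report, numbered 162 with DESeq2, 11 to 51 without single libraries and 66 without the 3. Loops that fell in both tissues numbered 1 to 4 without single libraries. The distance of reduced embryo loops gave a permutation p of 0.0319 at the 0.1 threshold. The cause was not tested. Tests of motifs and of start sites near anchors were not run.

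Replicate numbers gave no sign of pairing the samples. Deviations of same-numbered libraries correlated at -0.14 to 0.20 for RNA, -0.10 to 0.18 for embryos and -0.26 to -0.06 for wing discs. In turn, 5 of 18, 2 of 8 and 0 of 12 checks were best with the own number. With 2 wing disc libraries per genotype the deviations mirror each other, so each pair of genotypes gives 1 distinct value. The 12 wing disc checks are therefore not independent. With the replicate block 951, 45 and 410 genes, 3 embryo loops, 8, 0 and 8 wing disc loops and 8, 3 and 8 lists were called. With the Halo-Trl numbers crossed, 10 and 0 wing disc loops were called in delta-POZ and delta-Q.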

Other observations

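The tests of this part on ribosome biogenesis genes were fixed before the listed genes were looked at, except the test without 4 names; Myc and elav were looked up after the pattern or their values were seen.

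Genes for making ribosomes were lower in delta-POZ discs. The nucleolar genes Nop56 (57.7 ± 4.55 against 168 ± 9.8 CPM in Halo-Trl, n = 3, log2 -1.54, edgeR adjusted p = 3.23e-05) and Mybbp1A (11.3 ± 0.288 against 48.3 ± 2.68 CPM, log2 -2.09) were among those that prompted a list of 61 other names for ribosome biogenesis. The others were Nop60B (log2 -1.63), Fib (-1.43), nop5 (-1.74), Nopp140 (-1.41) and Nnp-1 (-1.20). All had been seen to fall in the same libraries, so the list asks whether related genes fell too. Of the 61 names, 11 matched no gene of the RNA table and 50 were tested. Among the 50, 4 belong to genes of other functions (pes, a scavenger receptor gene, Rrp1, a DNA repair gene, and the splicing helicase genes l(3)72Ab and pea). Of the 50, 27 fell and 0 rose in delta-POZ (42 adjusted over the list alone), with a median log2 fold change of -0.99 and 48 of 50 below 0. Without the 4, 27 of 46 fell and 0 rose (39 lower adjusted over the list alone), with a median of -1.02 (camera p = 3.12e-27, or p = 0.00951 with an estimated correlation). RpLP0-like is in both this list and that of ribosomal proteins. In delta-Q 0 were called (median -0.04), and between the deletions 22 were higher in delta-Q (38 higher and 1 lower adjusted over the list alone, median 0.85, camera p = 6.66e-29, or p = 0.0106 with an estimated correlation). Myc, which drives growth and ribosome production, stood at 255 ± 22 CPM in delta-POZ against 957 ± 134 in Halo-Trl and 935 ± 207 in delta-Q (log2 -1.91, SE 0.18, adjusted p = 2.84e-04 for delta-POZ).

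Technical explanations were weighed for this pattern. Without delta-POZ 2, the library with nervous tissue markers, the median stayed at -0.93, and it was -0.97 with RLE and with upper quartile normalization, which argues against that tissue and against the normalization as its source. Camera called the list lower in delta-POZ (p = 3.44e-26, or p = 0.0108 with an estimated correlation), and an effect of the POZ deletion on growth genes is a hypothesis that may account for it. A difference in larval age or line background was not tested and stays open.

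The neuronal gene elav was measured at 51.12, 74.03 and 66.88 CPM in Halo-Trl, 4.88, 137.02 and 3.36 in delta-POZ and 4.45, 9.28 and 9.24 in delta-Q (overlaps arg and a long non-coding RNA). Neither deletion gave a call (edgeR adjusted p = 0.856 and 0.48), but without delta-POZ 2 elav was lower in delta-POZ, and without the 3 libraries with most RNA of other tissues it was lower in both (log2 -4.09, adjusted p = 1.42e-04, and log2 -3.39, adjusted p = 7.01e-04); over all alternatives adjusted p reached 0.959 and 0.876.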
